A study of Danio rerio with 6 samples.

How the data were processed

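Polyadenylated RNA from zebrafish (Danio rerio) ventricles was sequenced as 6 libraries, 3 from ttna+/- fish and 3 from wild-type (WT) siblings. Per the labels' protocols, the fish were 6 months old, each library came from a pool of 6 ventricles, the 3 pools of a genotype were biological replicates, and reads were paired-end and 50 bases long. The ttna gene encodes titin, the giant spring-like protein of the sarcomere, and the mutant allele carries a truncating change in exon 201.

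The authors deposited 1 table per library with an annotated length, an effective length, an estimated count and a TPM value (a length-corrected relative abundance) for each of 57775 Ensembl transcripts. The estimated counts were not scaled to a common total, since their sums ranged from 28688112 in WT 1 to 44412410 in ttna+/- 3. Between 44.3% and 47.5% of the estimated counts, counts of 0 included, were whole numbers in a library, to within 1e-06 of a count. The rest were fractions left by dividing reads among transcripts that share sequence. The deposited TPM values equalled the estimated count over the effective length, rescaled to the same sum in each library, with a largest relative difference of 9.8e-06. The submitters' processing notes list TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and the builds Zv9 and GRCz11 without saying what each was used for. The column layout is that of the program kallisto, but the program that wrote these tables and the transcript annotation it used are not given in the sources used here. The series' design text names a DESeq approach with a threshold of more than 2-fold and an adjusted p under 0.05.

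The files identify each transcript by an Ensembl transcript ID alone, and 0 of the 57775 IDs occur in the gene tables used here, which list gene IDs, symbols and RefSeq accessions. Counts could therefore not be summed per gene. The planned comparisons of ttna itself, of 21 gene lists and 16 cell type marker lists, and of genes near ttna were not run, and every test below is per transcript. Isoforms and near-identical copies share reads, so a difference in 1 transcript can come from how reads were divided among its relatives as well as from its abundance. That uncertainty is not part of the tests.

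Estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with its default minimum count of 10, robust dispersion and robust fit, genotype as the only term). Adjusted p-values are Benjamini-Hochberg values over the 29950 transcripts that passed the filter, which held between 99.7% and 99.9% of each library's counts. A transcript was called at an adjusted p under 0.05 and a fold over 2, the threshold of the series' design text. The standard error of a log2 fold change was taken as its size over the square root of the test's F. The rule for named genes was fixed before the data were examined but needs gene symbols. In its place, after the files had been seen, the 2 transcripts with the smallest p in each direction were named. They came from those with a mean of at least 5 CPM (the count scaled to a fixed library size, with TMM factors) and no overlap between the groups. CPM without TMM factors was used for all other CPM limits, for transcripts apart by 2-fold or found on 1 side only, and for records described by their length. The TMM factors were 1.03, 0.96 and 0.93 in ttna+/- 1 to 3 and 1.09, 0.99 and 1.01 in WT 1 to 3.

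The alternatives set before the data were examined were DESeq2 1.42.0, limma-voom (limma 3.58.1), limma on log2(TPM + 1) and log2(TPM + 0.1), other scaling factors, other filters, a fold limit inside the test, a non-robust fit, an effective length offset, a replicate block and leaving out each library. Added after seeing the data were 1 surrogate variable (sva 3.50.0), the side of the leading component as a term, the length gap (annotated minus effective length) of each library as a term, removal of each library's trend on transcript length (lowess, span 0.3), thinning to the lowest total, a mean of at least 5 CPM, and leaving out each library under DESeq2. The main test, DESeq2, and edgeR with the surrogate variable, the length gap, the length trend removed or thinned counts were also run on all 10 splits of the 6 libraries into 3 and 3.

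The test was tried on simulated data with the real means, library sizes and dispersions of these 29950 transcripts, in which 200 transcripts were changed between ttna+/- and WT. Each transcript was drawn independently, so the simulation lacks any spread that the real libraries share across transcripts. Its share of unchanged transcripts among the calls also depends on the choice of 200. At an adjusted p under 0.05 edgeR called 2% of the 2-fold, 46% of the 4-fold, 94% of the 8-fold and 92% of the 16-fold changes, with 9 unchanged transcripts called. DESeq2 called 28%, 86%, 98% and 98% of them, with 119 unchanged transcripts called, 43.4% of its calls. The 2-fold limit removed none of these calls in either program.

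No 2 libraries were copies of one another. The mean squared difference between libraries of a group was at least 34.5 times the sampling noise of their counts (chi-square per degree of freedom). No column of per-sample values was left unmapped. Figures were drawn with matplotlib 3.10.9.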

Results

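Gene expression was measured by RNA sequencing in the ventricles of adult zebrafish heterozygous for a truncating allele of ttna and in their WT siblings, with 3 pooled libraries per genotype. Library totals ranged from 28688112 to 44412410 estimated counts. Each library had between 38698 and 40449 of the 57775 annotated transcripts above 0. The 20 most abundant transcripts of a library took 30.2% ± 2.52 of its counts in ttna+/- and 31.1% ± 4.01 in WT (SD, n = 3 per group, exact permutation test, two-sided p = 0.80).

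The libraries of the genotypes also differed in depth and fragment size. The ttna+/- libraries were deeper, at 42033680 ± 2060345 counts against 31833354 ± 2821225 in WT (SD, n = 3 per group). The annotated length of long transcripts exceeded the effective length, a gap set by the size of the sequenced fragments, by 168 ± 1.31 bases in ttna+/- and by 158 ± 4.35 bases in WT. Neither measure overlapped between the groups. For both the exact permutation test gave p = 0.1, two-sided, which is the smallest value that 3 libraries against 3 allow.

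Libraries of a genotype were not clearly more alike than libraries of different genotypes. Pearson's r of log2 CPM across transcripts, which are not independent replicates, ranged from 0.89 to 0.94 over the 6 pairs within a genotype and from 0.86 to 0.91 over the 9 pairs between genotypes. The first principal component held 39.6% of the variance. It placed ttna+/- 1, ttna+/- 3 and WT 1 on one side and ttna+/- 2, WT 2 and WT 3 on the other. The second component held 19.0%, with ttna+/- 1 and 2 at scores of 21.6 and 96.9, WT 1 and 2 at -78.4 and -61.8, and ttna+/- 3 and WT 3 at nearly the same score (9.57 and 12.13).

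**Figure D1:**
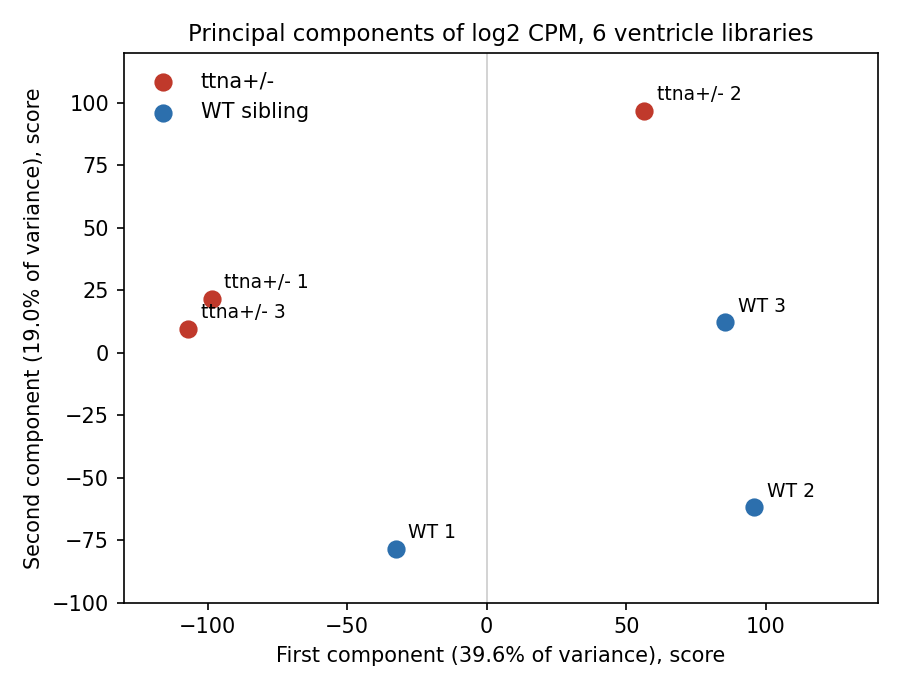
Scores of the 6 libraries on the first and second principal components of log2 CPM over 29950 transcripts, in units of log2 CPM, coloured by genotype. The first component (39.6% of the variance) puts WT 1 at -32.6 on the same side as ttna+/- 1 at -98.5 and ttna+/- 3 at -107, and ttna+/- 2 at 56.5 beside WT 2 and WT 3.

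The comparison of ttna+/- with WT hearts asks which transcripts differ in the adult ventricle when one copy of ttna is truncated. The files identify transcripts by ID alone, so neither ttna nor any other gene is named among them. Across transcripts with a mean of at least 5 CPM, here without TMM factors, 18 were more than 2-fold higher in each ttna+/- library than in any WT library, and 27 were more than 2-fold lower. The 8 splits of the libraries that follow neither genotype nor the first component gave 1 to 7 such transcripts, both directions together, and the split along the first component gave 562. That last split was drawn from the same data, so a high number there is partly built in. None of the differences between genotypes passed the adjusted threshold of the main test. The quasi-likelihood test of edgeR called 0 of 29950 transcripts, at an adjusted p under 0.05 with or without the 2-fold limit. The smallest adjusted p was 0.163. Unadjusted p-values under 0.05 were found for 3178 transcripts, 10.6% of those tested, and for 1933 (without ttna+/- 3) to 5114 (without ttna+/- 2) when 1 library was left out. With the length gap of each library, which follows genotype, as a term the number was 1367, and 5% of the transcripts tested would be 1497.5. With the same term the 8 other splits gave 372 to 831. Without that term the 8 other splits gave 371 to 1110, and the split along the first component 6738.

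ENSDART00000020253.6, a transcript of 2859 bases, had the smallest p of those higher in ttna+/- hearts. It stood at 114 ± 5.91 CPM in ttna+/- and at 33.0 ± 3.05 CPM in WT (SD, n = 3 per group), a log2 fold change of 1.79 ± 0.14 (SE). ENSDART00000105809.5, of 2349 bases, stood at 143 ± 28.1 CPM in ttna+/- and at 32.7 ± 3.48 CPM in WT, a log2 fold change of 2.12 ± 0.20 (SE). In the other direction, ENSDART00000187836.1, of 243 bases, stood at 142 ± 5.71 CPM in ttna+/- and at 340 ± 7.46 CPM in WT, a log2 fold change of -1.26 ± 0.13 (SE). ENSDART00000036939.7, of 1295 bases, stood at 179 ± 6.22 CPM in ttna+/- and at 429 ± 13.7 CPM in WT, also with a log2 fold change of -1.26 ± 0.13 (SE). The adjusted p of each in edgeR was 0.163. DESeq2 gave ENSDART00000020253.6 an adjusted p of 8.4e-25, ENSDART00000105809.5 one of 1.3e-15, ENSDART00000187836.1 one of 8.2e-18 and ENSDART00000036939.7 one of 1.6e-17. Besides DESeq2, limma on log2(TPM + 0.1) put the pair higher in ttna+/- under 0.05, at 0.037 and 0.028. Over the 24 alternatives the largest adjusted p was 0.871 for the pair higher in ttna+/-, with the length gap of each library as a term. For the pair lower it was 1.00 in the test against a 2-fold change, and 0.871 at most in the others. None of the 4 changed direction, which tells little, since they were chosen from these data for a small p and groups without overlap.

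**Figure D2:**
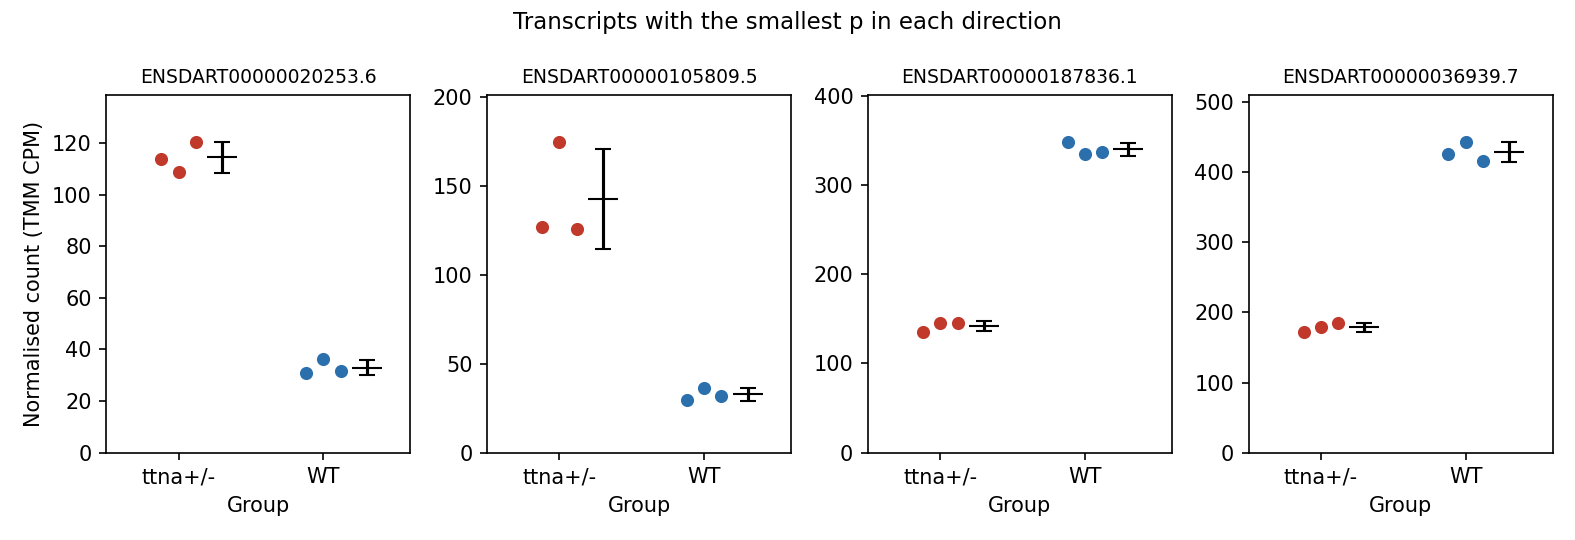
Normalised count (CPM with TMM factors, linear axes from 0) of the 2 transcripts with the smallest p in each direction, with 1 point per library and the mean and SD beside the points. ENSDART00000020253.6 lies between 109 and 121 CPM in ttna+/- and between 30.9 and 36.5 in WT, ENSDART00000105809.5 between 126 and 175 and between 29.7 and 36.5, ENSDART00000187836.1 between 136 and 146 and between 335 and 349, and ENSDART00000036939.7 between 172 and 184 and between 417 and 444.

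DESeq2, run because the series' design text names a DESeq approach, called 436 transcripts at an adjusted p under 0.05 and a fold over 2. Of these, 282 were higher and 154 lower in ttna+/- hearts. The mean was at least 5 CPM for 203 of them, 135 higher and 68 lower. The main test fitted 387 of the 436, and in all 387 the direction was the same and the unadjusted p of edgeR was under 0.05. Both programs read the same counts with the same single term, so this is no independent check of the calls. The median length was 2506.5 bases for transcripts called higher and 1496 bases for those called lower, against 1966 bases for all transcripts fitted by edgeR. Over all of these the median log2 fold change also rose with length, from -0.125 in transcripts of up to 500 bases to 0.198 in those over 8000 bases.

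Simulated data had each transcript's own spread, 200 changed transcripts, and no component shared across transcripts. There, at an adjusted p under 0.05 and a fold over 2, 43.4% of the DESeq2 calls and 7.14% of the edgeR calls were of unchanged transcripts. These shares depend on the 200 chosen and cannot be carried over to the real calls. The DESeq2 count also depended on single libraries. It rose to 1727 (1370 higher, 357 lower) without ttna+/- 2 and to 1040 (807 higher, 233 lower) without WT 1. The first component places ttna+/- 2 and WT 1 with libraries of the other genotype. Leaving out either lets the genotype comparison follow that component more closely. The excess of higher calls was gone without ttna+/- 1 (182 higher, 182 lower) and small without ttna+/- 3 (179 higher, 164 lower). With the side of the first component as a term, edgeR called 0 transcripts and gave an unadjusted p under 0.05 for 4044. Limma-voom called 0 transcripts, and limma called 1 on log2(TPM + 1) and 8 on log2(TPM + 0.1).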

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

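The effective lengths, which the main test does not use, held a difference between the genotypes: the gap between annotated and effective length averaged 168.4 bases in ttna+/- and 157.9 bases in the WT control libraries, and the lowest ttna+/- library (167 bases) lay above the highest WT library (161 bases). Groups of 3 libraries are too small for a check of single outlying samples.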

How the results depend on the processing

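The count of 0 transcripts held, with and without the 2-fold limit, under 2 other scalings, 2 other filters, limma-voom, the effective length offset, the non-robust fit, and each library left out in turn (range 0 to 0), and under a fold limit inside the test. It also held under the 6 settings added after seeing the data. DESeq2 called 436 transcripts past the 2-fold threshold and 589 at an adjusted p alone, and limma called 1 on log2(TPM + 1) and 8 on log2(TPM + 0.1), each count the same with and without the 2-fold limit; the cause of these differences was not established. Leaving out 1 library moved the DESeq2 count between 343 and 1727. With the replicate block edgeR also called 0 transcripts (3365 at an unadjusted p under 0.05). No clear pairing by replicate number was seen. The deviations of same-numbered libraries from their group means correlated at 0.24, 0.20 and -0.20 across transcripts, and ttna+/- 2 deviated with WT 3 (0.202) as much as with WT 2 (0.197). The first component puts ttna+/- 3 and WT 3 on opposite sides, so these correlations could miss a modest pairing. The replicate numbers are those of the titles. Those in the names of the WT tables run 1 higher, and by them ttna+/- 2 with WT 1 correlated at -0.38 and ttna+/- 3 with WT 2 at -0.07. The alternatives planned for ttna, the gene lists and genes near ttna gave no value, since transcript IDs were not paired with genes. DESeq2 gave no adjusted p for 14029 transcripts with counts. Leaving out 1 library moved the number at an unadjusted p under 0.05 between 1933 and 5114, above 3178 only without ttna+/- 2 (5114) or WT 1 (3865). With the length gap, which follows genotype, as a term it was 1367. Thinning all libraries to the lowest total left 3061 transcripts at an unadjusted p under 0.05, against 3178.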

Other observations

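The tests of library depth, fragment length, length as the whole cause, zero counts, exchanged samples, other splits, the run of 13 records and the longest transcripts were chosen only after the results they bear on were seen. Without gene names, some transcripts can still be described by their annotated length. A run of 13 abundant records in the files has lengths that equal, in order, those of the 13 protein-coding genes of the zebrafish mitochondrial genome in the RefSeq table (13 of 13 lengths, against at most 2 in any other run). A candidate explanation is that they are the mitochondrially encoded mRNAs, although no ID in the gene tables used here pairs them. Read that way, they took 14.1% ± 1.97 of counts in ttna+/- and 14.3% ± 2.37 in WT (SD, n = 3 per group, exact permutation test, two-sided p = 0.90). The log2 fold change of 11 of the 13 lay within 0.2 of 0 on either side. The records with the lengths of ND5 and ND6, subunits of respiratory complex I, had log2 fold changes of 0.59 ± 0.32 and 0.93 ± 0.40 (SE), with edgeR adjusted p of 0.537 and 0.480. Both records had their highest values in ttna+/- 1 and 3, a pattern over single libraries that was not tested. The ND5 record stood at 2024, 1174 and 2632 CPM in ttna+/- 1 to 3 and at 1190 to 1542 in WT, and the ND6 record at 678, 298 and 825 CPM and at 251 to 379 in WT.

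4 transcripts are longer than 60000 bases (67298, 78795, 82380 and 88553), and the next longest has 45657. They lie at 2 places in the files, as many as the 2 genes named titin in the gene table, and titin is the largest known vertebrate protein. A candidate explanation is that they are titin transcripts, among them those of ttna. The gene tables used here hold none of the IDs and cannot settle it. Their sum was 7188 ± 3834 CPM in ttna+/- and 4140 ± 3704 CPM in WT (SD, n = 3 per group, exact permutation test, two-sided p = 0.20). By library the sum was 8536, 2862 and 10166 CPM in ttna+/- 1 to 3, and 8363, 2617 and 1440 CPM in WT 1 to 3. It followed the leading split without overlap, at 8363 or more on the side of ttna+/- 1, ttna+/- 3 and WT 1 and at 2862 or less on the other. The 82380-base transcript stood at 1525, 1622 and 1161 CPM in ttna+/- 1, ttna+/- 3 and WT 1. It stood at 16.7 CPM in WT 2, at under 1 count in ttna+/- 2 and at 0 in WT 3, where 3 counts would be 0.092 CPM.

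The split of ttna+/- 1, ttna+/- 3 and WT 1 from the other libraries was drawn from the first component of the same values that were then tested. A high count is thereby partly built in, and its adjusted p carries no error rate. The split called 1576 transcripts at an adjusted p under 0.05 with edgeR, against 0 for genotype and 0 for each of the 8 remaining splits. It was one-sided: 557 transcripts with a mean of at least 5 CPM were more than 2-fold higher in each of these 3 libraries than in any other, and 5 were lower, and the 557 had a median length of 4835 bases against 2409 for all such transcripts. Depth and fragment length do not explain it: the split called 1664 transcripts with every library thinned to the lowest total and 1639 with the length gap as a term, against 0 in each of the 8 remaining splits treated the same way. Removing each library's average trend on annotated length left 705 calls, against 0 in each of the 8 remaining splits. A length-dependent yield, such as RNA breakage or capture would give, may thus account for part of the split. The average trend was not the whole of it. Transcripts of equal length can differ in yield, so the 705 calls cannot exclude such a yield as the whole cause. If ttna+/- 2 and WT 1 had been exchanged, this split would be the genotype split, and the 0 and the 1576 calls would change places. Against such an exchange, the split as labelled gave 436 DESeq2 calls, and the highest of the 8 remaining splits 98. But depth and length gap also followed the labels, and a difference in how the libraries were made could give that excess. The split as labelled also parts the libraries with the largest first-component scores in size, which could add to it. An exchange stays open. No biological explanation was tested, because the labels as given name nothing that divides the libraries this way.

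DESeq2 called 436 transcripts for genotype, and edgeR 0. Transcripts without reads in some library do not account for most of the DESeq2 calls. Of the 589 at an adjusted p under 0.05, with no fold limit, 111 (18.8%) had a library at 0. The 436 are among the 589, so at most 111 of the 436 had such a library. Their own share was not computed. Whether spread along the leading component hides genotype differences from edgeR stays open. With 1 surrogate variable, which correlated with the first component at 0.98 (absolute value), edgeR called 0 for genotype and 0 in each of the 8 remaining splits; the criterion set beforehand would have counted this against the explanation, but 2 counts of 0 cannot be ranked. The smallest adjusted p moved from 0.163 to 0.073, and the transcripts at an unadjusted p under 0.05 from 3178 to 3898. In the simulation with 200 changed transcripts, at the same thresholds as the 436, 119 of DESeq2's calls, 43.4%, were of unchanged transcripts. That share depends on the 200 chosen and on transcripts drawn independently, so it cannot be carried over to the 436. How many of the 436 may be real stays open. A genotype difference stays open: the genotype split gave 436 DESeq2 calls, against 21 to 98 in the 8 remaining splits, and 45 transcripts apart by more than 2-fold, against 1 to 7. Depth and length gap also followed genotype, so the excess cannot be told from a difference in how the libraries were made. The 8 remaining splits are not equal to genotype along the first component either. Genotype parts the libraries with the largest scores in size, ttna+/- 1 and 3 (-98.5 and -107) from WT 2 and 3 (95.8 and 85.5). Part of the excess could come from that component. With the length gap as a term, edgeR gave an unadjusted p under 0.05 for 1367 transcripts, against 372 to 831 in the 8 remaining splits.

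With 10 splits of the 6 libraries, no share under 0.05 can be reached. For the edgeR count with the 2-fold limit, the real value was 0 and the highest other 1392, and without the limit 0 and 1576. That 10 of the 10 splits gave as many in both cases follows from the real count being 0 and tells nothing. For DESeq2, 2 of the 10 gave as many as the real 436, the genotype split itself included. The highest other, 2768, was the split along the leading component, which points to a structure of the samples that crosses genotype as labelled.

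Above 1 CPM in every library of one genotype, with no rounded count in the other, were 14 transcripts, 9 only in ttna+/- and 5 only in WT. The 8 remaining splits gave 1 to 7 and the split along the leading component 28. These counts can include transcripts already counted as apart by more than 2-fold.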
